A study of Mus musculus with 6 samples.

How the data were processed

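Total RNA of sorted cardiac myeloid cells was labelled and hybridised to Illumina mouse expression arrays, which read each transcript through a bead-bound probe. The values used are the linear probe intensities that the authors deposited for 6 arrays, 3 from P1 hearts and 3 from P14 hearts, and groups and replicate numbers were taken from the sample titles. All 6 columns held the same set of sorted intensities apart from rounding and ties, so the values the authors deposited had been quantile-normalized between arrays, on a linear scale, with no centring. The software that did so is not given in the sources used here. Background had not been subtracted, since the lowest intensity was 96.7 and the most frequent value lay at 112. A further table of scanner signals was not used here: its 24 columns carry chip positions as names, which match no sample label, and columns were never assigned from their values. Detection p-values, chip positions and scan batches were therefore not used, and the plan made before the data were examined, background correction with control of detection p, was replaced by its written fallback of taking log2 of the normalized intensities.

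Probes were named through a table of the platform's annotation. Of 45281 probes, 34885 had a single gene symbol, 18 had several and 10378 had none, and no gene was named from the last 2 kinds. Gene symbols were checked through Entrez identifiers against RefSeq genes of GRCm38.p6. That table held 34807 of the single-symbol probes, and 0 symbols needed an update. A floor was set at 3 standard deviations above the most frequent log2 value, with the standard deviation taken from the mirrored values below it, which gave an intensity of 126. A probe was kept when it exceeded the floor on at least 3 arrays, which left 19106 probes, 16266 of them with a gene. Each gene was represented by its probe with the highest mean, which gave 10506 genes tested, 3920 of them with more than 1 kept probe. For a gene whose tested probe stayed below the floor on every array of a group, the fold of that probe is given as a lower bound against the floor.

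Log2 intensities were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with a term for group only. Benjamini-Hochberg adjustment ran over all genes tested with a threshold of 0.05, and a stricter count also required an absolute log2 fold change of at least 1. Log2 fold changes are P1 minus P14, and their errors are limma's standard errors with n = 3 arrays in each group. Because background was left in, folds are understated, most where a group lies near background. Each of 25 gene lists, fixed before the data were examined, was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and members were also counted with p-values adjusted over the list alone. Camera asks whether a list's genes shifted relative to the other genes on the array.

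Genes are named by a rule fixed before the data were examined: the 12 largest absolute log2 fold changes in each direction among genes past the threshold with no overlap between groups, up to 4 members of each list with the largest change past the threshold or, where none passed, the 2 with the highest mean, and fixed sets of sorting and polarization genes. Genes named outside the rule were chosen after their values were seen: the single members running against a list's direction, Folr2, Timd4, C1qa, Mertk, Ccr2, Vegfa, Ltf, Ngp, S100a8, Prtn3 and Gstp1, and the genes named for granulocytes or for disagreement between probes.

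The fit was tested on simulated data with the real genes' means and their spreads as moderated by eBayes, drawn independently between genes. Over 20 runs on 10506 genes for this comparison, 82.2% of genes changed by 0.5 on the log2 scale were found, 99.0% of those changed by 1 and all 1000 of those changed by 2, and 5.95% of calls were unchanged genes. Each run changed only a small share of the genes, whereas 20.04% of genes were called in the data. These rates therefore need not carry over to the data. A shift of 0.5 in the 25 genes of the resident macrophage list was found in 20 of 20 runs, with the preset as with the estimated correlation. Independent genes do not correlate, whereas in the data the estimated correlation of that list was 0.202. The runs therefore do not show how often camera with an estimated correlation finds such a shift in these data.

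Alternatives covered the filter, the probe rule, the variance model, array weights, the replicate number as a block, normexp background correction, a further cyclic loess step, leaving out each array, and other gene set tests. When an array was left out, each gene's probe was chosen anew by the highest mean over the arrays that remained. The number of arrays limits the precision of every value.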

Results

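The cells studied were CD11b-positive, Ly6G-negative myeloid cells, a gate that takes in macrophages and monocytes and is meant to leave out neutrophils. They were sorted from the hearts of ICR mice, an outbred strain, 3 days after myocardial infarction by tying off the left anterior descending coronary artery. The infarct was made at day 1 after birth (P1) or at day 14 (P14), and 3 arrays were run for each age with both sexes in the material. The mouse heart regenerates after injury in the first days of life and loses that capacity soon after, so the comparison asks how the macrophages of the 2 ages differ after the same injury. Nothing in the labels says whether arrays came from separate animals or pools, and p-values then measure only the spread between these samples, which may be technical. All arrays shared a median intensity of 121, and 18917 to 18937 probes per array exceeded the floor of 126.

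At P1 the sorted material held more transcript of the stefin Stfa1, of genes of tissue-resident macrophages, of cardiomyocyte genes and of Igf2, and less of interferon-stimulated, antigen-presentation and monocyte genes than at P14. The list calls come from camera at a preset correlation: with an estimated correlation its adjusted p was 0.499 to 0.647 for each, and a split of the arrays that mixes the ages also gave 10 called lists. Stfa1, a stefin that inhibits cysteine proteases, was 14.3-fold higher in P1 (log2 fold change 3.84 ± 0.315, SE, n = 3 per group, adjusted p = 0.00137), and 23.5-fold after normexp background correction. Fcna, the lectin ficolin A, was 6.41-fold higher (2.68 ± 0.303, adjusted p = 0.00227), and Igf2, a fetal growth factor, was 3.90-fold higher (1.97 ± 0.287, adjusted p = 0.00482). In the other direction, Pdpn, which encodes the surface glycoprotein podoplanin, was 3.36-fold lower in P1 (-1.75 ± 0.255, adjusted p = 0.00480). Retnlg, which encodes a resistin-like protein of myeloid cells, was 3.11-fold lower (-1.63 ± 0.154, adjusted p = 0.00151).

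Of 10506 genes tested, 1094 were higher and 1011 lower in P1 at an adjusted p under 0.05, together 20.04% of genes. The groups did not overlap in 38.5% of genes, against 10% by chance for 3 against 3. Most differences were small: the median absolute log2 fold change among the 2105 called genes was 0.43, and 51 higher and 32 lower genes also reached an absolute log2 fold change of 1. The first principal component held 59.2% of the variance and separated the ages, and the second, with 15.4%, set P14 replicate 3 (15.4) apart from P14 replicates 1 and 2 (-8.18 and -5.61). Counts fell to 515 higher and 536 lower without P1 replicate 3, to 627 and 614 without P14 replicate 1, and to 580 and 611 without P14 replicate 2. Of the 87 calls among genes named by the fixed rule, 21 were lost under at least 1 setting that kept all arrays, and 32 were lost without at least 1 array. For each of these the highest adjusted p is given below with the array left out. That array was often not the only one. Removing any 1 of 5 arrays ended the calls of Isg15, Usp18, S100a4, H2-DMb2, Ptprc and Tspan33. Removing any 1 of 4 arrays ended those of Bst2, Chil3, Chil4, Cd74, H2-DMb1, Igf1, Marco, Sparc, Aqp1, Ccl4 and Fscn1. Of genes named outside the rule, Ltf lost its call without any 1 of 5 arrays, and Ccr2 and Prtn3 without any 1 of 4. After normexp background correction 124 higher and 95 lower genes reached a log2 fold change of 1.

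Among the 12 largest differences upward in P1 under the naming rule, stefin and stefin-like genes made up 4: Stfa1, Cstdc4 (6.71-fold, adjusted p = 0.00659), Stfa2 (4.23-fold, adjusted p = 0.0264) and Cstdc5 (3.36-fold, adjusted p = 0.00510, with 2 of 3 P14 arrays above the floor). These genes are near-identical neighbours on chromosome 16 whose probes may cross-hybridise, so their separate levels are uncertain, and Stfa2 lost its call without P14 replicate 2 (adjusted p = 0.0805). The log2 fold changes of the 2 Stfa2 probes differed by 1.05. No fixed list covered these genes, which were grouped after their values were seen. Within P1 some varied with granule genes: on replicates 1, 2 and 3 the log2 intensity of Stfa1 was 11.48, 11.01 and 12.29 and that of the granule gene Camp 8.71, 7.70 and 9.39, while the granule gene S100a9 stood in another order, at 11.10, 11.37 and 11.91. After normexp the folds of Stfa2 and Cstdc5 were 7.08 and 7.85. Gstp2, a glutathione S-transferase, was 4.25-fold higher (2.09 ± 0.124, adjusted p = 0.000601; 6.39-fold after normexp), and so was its close paralog Gstp1 by 3.23-fold (adjusted p = 0.00533), with the same uncertainty between copies and a span of 1.33 between the log2 fold changes of its 3 probes. Slc40a1, the iron exporter ferroportin, was 3.30-fold higher (1.72 ± 0.294, adjusted p = 0.00786). The 12 largest downward differences under the same rule included Hal, histidine ammonia-lyase (2.81-fold lower, adjusted p = 0.00137), Gpr171, a G protein-coupled receptor (2.50-fold lower, adjusted p = 0.00137), Errfi1, a feedback inhibitor of EGF receptor signalling (2.23-fold lower, adjusted p = 0.000898), and Rgcc, a regulator of cell cycle progression (2.22-fold lower, adjusted p = 0.00549).

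**Figure D1:**
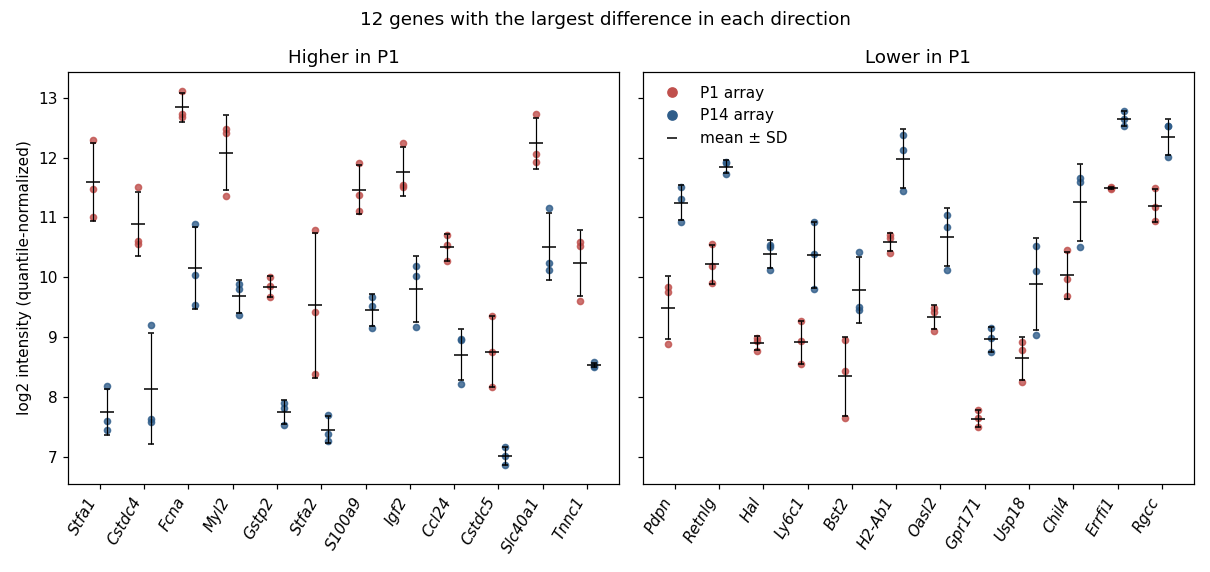
Log2 quantile-normalized intensity (vertical axis) of the 12 genes with the largest difference upward in P1 (left) and downward in P1 (right); each point is an array, bars are the mean and SD of 3 arrays. Only genes whose P1 and P14 arrays do not overlap could be shown under the naming rule, and the 3 P1 arrays of Stfa2 spread most (SD 1.21).

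Genes of resident cardiac macrophages, the embryonically seeded population that persists in the tissue, were higher in P1. Of 25 tested members, 10 were higher and 1 lower (14 higher and 1 lower when adjusted over the list alone), and the list mean was 0.64 (camera adjusted p = 3.82e-06; adjusted p = 0.499 with an estimated correlation). Fcna led the list, followed by the chemokine Ccl24 (1.79 ± 0.206, 3.46-fold, adjusted p = 0.00237), the fractalkine receptor Cx3cr1 (1.61 ± 0.198, 3.05-fold, adjusted p = 0.00272) and Lyve1, a hyaluronan receptor of perivascular macrophages (1.18 ± 0.0901, 2.26-fold, adjusted p = 0.00133). Mrc1, the mannose receptor, was 2.02-fold higher (adjusted p = 0.00152). The exception was Cbr2, a carbonyl reductase, with a log2 fold change of -0.79 (adjusted p = 0.00779). Folr2 (0.51), Timd4 (0.39), C1qa (0.19) and Mertk (0.19) did not pass, and without single arrays their log2 fold changes ranged from 0.32 to 0.60, 0.19 to 0.52, -0.05 to 0.41 and 0.06 to 0.36.

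Markers of monocyte-derived cells went the other way. Of 17 members, 8 were lower in P1 and 1 was higher, both over all genes and adjusted over the list alone, with a mean of -0.41 (camera adjusted p = 0.000527; adjusted p = 0.499 with an estimated correlation). Ly6c1, a gene of the Ly6C surface antigens, was 2.74-fold lower (-1.45 ± 0.277, adjusted p = 0.0116). Its probe may also read the near-identical paralog Ly6c2, and which of the 2 it measured is not known, so the value alone does not point to monocytes. The list's mean log2 deviation was 0.37 and 0.25 on P14 replicates 1 and 2 but -0.00769 on P14 replicate 3, and between -0.30 and -0.11 on the P1 arrays. The number of lower members was 5 without P1 replicate 3 and 5 without P14 replicate 2. Thbs1, the matrix glycoprotein thrombospondin, was 1.87-fold lower (-0.91 ± 0.108, adjusted p = 0.00258) and the integrin Itgb7 1.71-fold lower (adjusted p = 0.00690). Ccr2, the receptor that draws monocytes to injured tissue, had a log2 fold change of -0.47 (adjusted p = 0.0276; 0.0852 without P14 replicate 2). The calcium-binding protein gene S100a4 was 1.57-fold lower (adjusted p = 0.0386), a call lost without P1 replicate 3 (adjusted p = 0.121). The member higher in P1 was F13a1, the A chain of a coagulation factor, at 0.52 (adjusted p = 0.0157; 0.0524 without P14 replicate 2).

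Among the sorting and pan-macrophage genes, Csf1r, the receptor for the growth factor that maintains macrophages, was 1.77-fold higher in P1 (0.82 ± 0.0950, adjusted p = 0.00237), and Ptprc, the leukocyte antigen CD45, was 1.34-fold lower (-0.42 ± 0.101, adjusted p = 0.0255; 0.0740 without P1 replicate 2). Itgam, which encodes CD11b, had a log2 fold change of -0.23 ± 0.146 (adjusted p = 0.316), and Adgre1, which encodes F4/80, one of -0.34 ± 0.146 (adjusted p = 0.141). The list of 12 gate and pan-macrophage markers had 1 member higher and 1 lower (2 and 1 adjusted over the list alone) and did not shift as a whole (camera adjusted p = 0.923). No probe was named Ly6g in the annotation used.

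Interferon-stimulated genes, which encode antiviral proteins, were lower in P1. Of 33 members 11 were lower and 0 higher, and 20 were lower when adjusted over the list alone. Without single arrays the number of lower members was 6 (P1 replicate 1 or 2), 3 (P1 replicate 3 or P14 replicate 1), 5 (P14 replicate 2) or 22 (P14 replicate 3), and with all arrays it was 4 with no filter, 7 with trend and robust eBayes, and 19 with array weights. The log2 fold change was negative in all but 4. The list mean was -0.59 (camera adjusted p = 2.33e-06; adjusted p = 0.566 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like gene, was 2.51-fold lower (-1.33 ± 0.223, adjusted p = 0.00759), and Bst2, the antiviral tether tetherin, was 2.72-fold lower (-1.44 ± 0.357, adjusted p = 0.0274). Isg15, a ubiquitin-like modifier, was 2.36-fold lower (adjusted p = 0.0497) and Usp18, which removes that modifier, 2.35-fold lower (adjusted p = 0.0442). The last 3 calls were each lost on removal of any 1 of several arrays, 4 for Bst2 and 5 for Isg15 and Usp18. Adjusted p was highest without P14 replicate 1 for Bst2 (0.0738). For Isg15 and Usp18 it was highest without P1 replicate 3 (0.149 and 0.136). The mean log2 deviation of the list was 0.52 and 0.47 on P14 replicates 1 and 2 but -0.11 on P14 replicate 3, which lay below P1 replicate 2 (-0.07), so the ages overlapped.

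Antigen presentation genes were lower as well. Of 11 MHC class II genes 6 were lower and 1 higher in P1 (7 and 1 adjusted over the list alone), with a mean of -0.51 (camera adjusted p = 0.00897; adjusted p = 0.499 with an estimated correlation). The lower members numbered 3 without P1 replicate 1 and 2 without P1 replicate 3, P14 replicate 1 or P14 replicate 2, and with all arrays 3 with no filter. H2-Ab1, a class II beta chain, was 2.63-fold lower (-1.39 ± 0.217, adjusted p = 0.00585). Cd74, the invariant chain, was 1.59-fold lower (adjusted p = 0.0310; 0.0893 without P14 replicate 2), and the peptide exchange genes H2-DMb1 (1.65-fold lower, adjusted p = 0.0312) and H2-DMb2 (1.51-fold lower, adjusted p = 0.0491) lost their calls without P1 replicate 3 (0.103 and 0.146). With the mean of its probes H2-DMb2 had a log2 fold change of -0.28 (adjusted p = 0.0780). The member higher in P1 was Ifi30, a lysosomal thiol reductase, at 0.43 (adjusted p = 0.00702). Of 20 MHC class I genes 4 were lower and 0 higher (7 lower adjusted over the list alone), with a mean of -0.38 (camera adjusted p = 0.000193; adjusted p = 0.499 with an estimated correlation). Without P1 replicate 2 or P14 replicate 3, 7 were lower, as with array weights, and 8 with the mean of probes. The 4 were H2-T23 (-1.07 ± 0.169, adjusted p = 0.00621), H2-K1 (-0.92 ± 0.138, adjusted p = 0.00533), H2-Q8 (-0.78 ± 0.154, adjusted p = 0.0133) and the peptide transporter subunit Tap2 (-0.73 ± 0.0955, adjusted p = 0.00333). The H2 genes are near-identical and polymorphic in an outbred strain, so the level of each copy is uncertain.

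**Figure D2:**
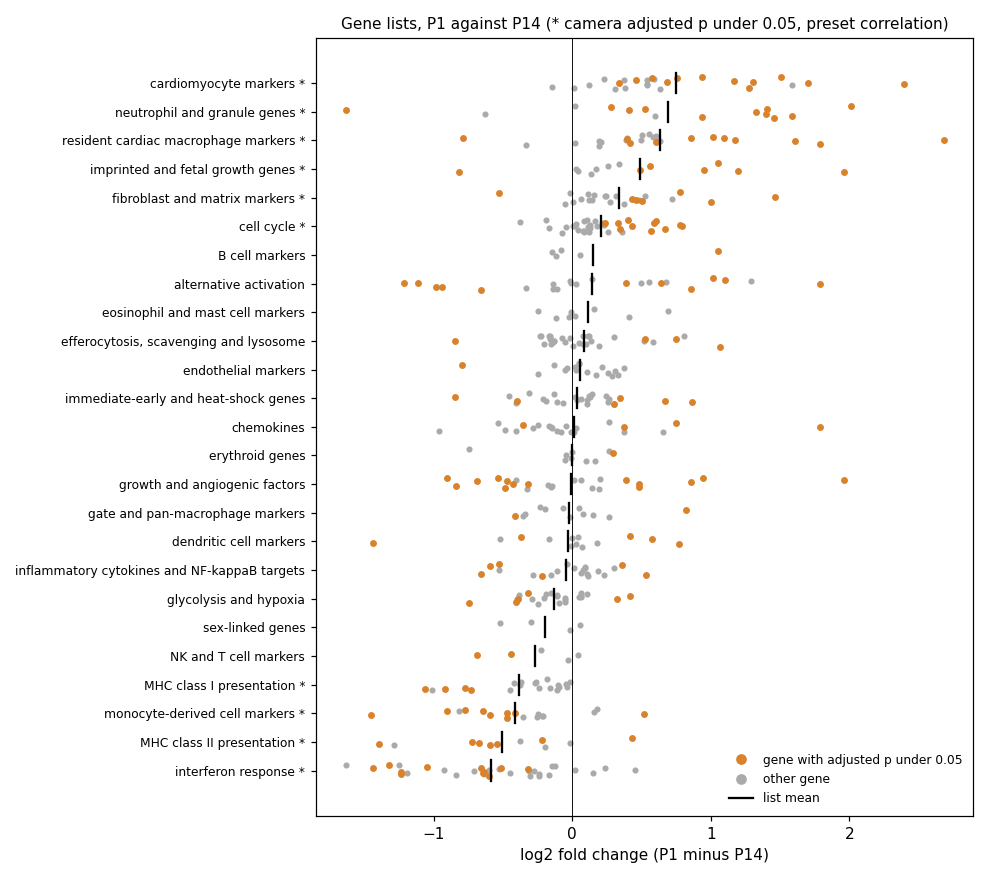
Log2 fold change (P1 minus P14, horizontal axis) of every tested gene in each of 25 lists, ordered by list mean (black bar); orange points are genes with an adjusted p under 0.05, grey points the others, and a star marks lists with a camera adjusted p under 0.05 at the preset correlation. Cardiomyocyte markers have the highest mean (0.75) and interferon response genes the lowest (-0.59).

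Genes often used to place macrophages between inflammatory and reparative states did not move as a block. Arg1, arginase, was bright at both ages (intensity 9013 in P1 and 8839 in P14) with a log2 fold change of 0.03 ± 0.250 (adjusted p = 0.954), Il1b had 0.09 ± 0.0730 (adjusted p = 0.433) and Tnf 0.23 ± 0.112 (adjusted p = 0.198). Il10, an anti-inflammatory cytokine, was 1.97-fold lower in P1 (-0.98 ± 0.145, adjusted p = 0.00505), whereas Mrc1 was higher, as above. Nos2 stayed below the floor on every array with both of its probes. Of 23 alternative activation genes, 6 were higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.801). Ccl24 and the lectin gene Mgl2 (2.15-fold, adjusted p = 0.0147; 0.0515 without P14 replicate 1) were higher, while the chitinase-like paralogs Chil3 (2.17-fold lower, adjusted p = 0.0340) and Chil4 (2.33-fold lower, adjusted p = 0.0317) were lower. Both of these calls were lost without P14 replicate 2 (0.0950 and 0.0988), and their probes may not separate the copies.

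In the list of inflammatory cytokines and NF-kappaB targets, 2 of 21 genes were higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.801), with a mean of -0.05 and a median of 0.06. The cytokine Il1a was 1.45-fold higher (adjusted p = 0.0234), and Traf1, an adaptor of TNF receptors, 1.58-fold lower (adjusted p = 0.0129), as were the costimulatory gene Cd80 (1.51-fold, adjusted p = 0.0157) and Tnfaip2 (1.45-fold, adjusted p = 0.00647; with the mean of its probes -0.21 and 0.113). Without P1 replicate 3 the calls of Il1a, Traf1 and Cd80 were lost (0.0821, 0.296 and 0.0588). The Traf1 log2 fold change was then -0.16 in place of -0.66, but it came from the gene's other probe, which now had the highest mean. The lost call of Traf1 therefore does not measure the left-out array alone. Of 22 chemokines, 3 were higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.841), and the list mean (0.01) was above 0 while its median (-0.10) and camera's direction were below. Beside Ccl24, Ccl3 was 1.68-fold higher (adjusted p = 0.00444) and Ccl4 1.30-fold higher (adjusted p = 0.0304; 0.0961 without P14 replicate 2). The neutrophil attractant Cxcl1 was 1.28-fold lower (adjusted p = 0.00873).

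Growth factor genes split. Of 24 growth and angiogenic factors 6 were higher and 8 lower in P1 (6 and 10 adjusted over the list alone; camera adjusted p = 0.381). Besides Igf2, Mmp9, a matrix metalloproteinase, was 1.92-fold higher (0.94 ± 0.175, adjusted p = 0.0107) and Igf1 1.81-fold higher (adjusted p = 0.0260; 0.0874 without P1 replicate 3), while Thbs1 and the angiogenic factor Vegfa (-0.84, adjusted p = 0.00174) were lower. Imprinted and fetal growth genes were higher in 6 of 13 and lower in 1 (9 and 1 adjusted over the list alone), with a mean of 0.49 (camera adjusted p = 0.000527; adjusted p = 0.499 with an estimated correlation). After Igf2 came Dlk1, at least 2.07-fold higher (adjusted p = 0.00137), Grb10, 2.07-fold higher (adjusted p = 0.00232; its 2 probes differed by 1.08), and Mest, at least 1.79-fold higher (adjusted p = 0.00137). After normexp the fold of Grb10 was 3.15. P1 replicate 2 had the highest list deviation (0.38, against 0.18 and 0.17 on P1 replicates 1 and 3) and the highest log2 intensity of Igf2 (12.24, against 11.51 and 11.55), and it was also the array highest in cardiomyocyte (0.69) and fibroblast (0.40) markers. Igf2 was higher on P1 replicate 1 than on any P14 array (10.20 at most). The cardiomyocyte deviation of P1 replicate 1, -0.03, was also above those of the P14 arrays (-0.38 to -0.37). That array therefore does not part Igf2 from cardiomyocyte transcripts, and the cells that gave the imprinted transcripts are not settled by these values. The lower member was Igf2r, the receptor that clears Igf2, at -0.82 (adjusted p = 0.00324).

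Cell cycle genes were modestly higher in P1. Of 36 members 11 were higher and 0 lower (11 and 1 adjusted over the list alone), with a mean of 0.21 (camera adjusted p = 0.000527; adjusted p = 0.571 with an estimated correlation). The list's mean log2 deviation nearly coincided on P1 replicate 2 (0.00895) and P14 replicate 3 (-0.0103), against 0.18 and 0.12 on the other P1 arrays and -0.15 on both other P14 arrays. The higher members numbered 6 without P1 replicate 3 or P14 replicate 1, and 5 without P14 replicate 2. Top2a, which untangles DNA, was 1.73-fold higher (0.79 ± 0.0839, adjusted p = 0.00196), the mitotic kinases Cdk1 and Aurkb 1.72-fold and 1.59-fold higher (adjusted p = 0.00196 and 0.00206), and the thymidine kinase Tk1 1.52-fold higher (adjusted p = 0.0202; 0.0725 without P1 replicate 3). With the mean of their probes Top2a stood at 0.46 and Tk1 at 0.29 (adjusted p = 0.180 for Tk1).

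Neutrophil and granule genes were higher in P1 in 10 of 14 and lower in 1 (10 and 2 adjusted over the list alone), with a mean of 0.69 (camera adjusted p = 0.000527; adjusted p = 0.499 with an estimated correlation). The higher members numbered 5 without P14 replicate 1 and 6 without P14 replicate 2. S100a9, a calprotectin subunit, was 4.03-fold higher (2.01 ± 0.208, adjusted p = 0.00180), and Mpo, myeloperoxidase, at least 2.65-fold higher by its tested probe (adjusted p = 0.000254). The 4 Mpo probes spanned 1.29, and their mean gave a log2 fold change of 0.71 (adjusted p = 0.00138) against 1.45. Camp, a cathelicidin, was 3.01-fold higher (adjusted p = 0.0207), with 1 of 3 P14 arrays above the floor, and lost its call without P14 replicate 1 (0.0651). After normexp the fold of Camp was 6.65. Ngp (at least 2.38-fold), S100a8 (1.32), Ltf (1.40) and Prtn3 (0.94) were also higher, and the calls of Ltf and Prtn3 were lost without P1 replicate 3 (0.132 and 0.0911). Retnlg was the lower member.

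Transcripts of other cardiac cells were present in the sorted material and differed between the ages. Of 25 cardiomyocyte genes 12 were higher in P1 and 0 lower (21 higher adjusted over the list alone), with a mean of 0.75 (camera adjusted p = 1.51e-07; adjusted p = 0.499 with an estimated correlation). Without single arrays the number of higher members was 20 (P1 replicate 1), 9 (P1 replicate 2), 7 (P1 replicate 3 or P14 replicate 1), 6 (P14 replicate 2) or 8 (P14 replicate 3). With all arrays it was 7 with no filter, 17 with array weights and 18 after normexp at offset 16. Myl2, a ventricular myosin light chain, was 5.27-fold higher (2.40 ± 0.287, adjusted p = 0.00259), Tnnc1, cardiac troponin C, 3.25-fold (adjusted p = 0.00390), Myl3 2.84-fold (adjusted p = 0.0102) and Actn2, sarcomeric alpha-actinin, 2.47-fold (adjusted p = 0.0104). The list's mean log2 deviation was -0.03, 0.69 and 0.47 on the 3 P1 arrays and between -0.38 and -0.37 on the P14 arrays. Fibroblast and matrix genes were higher in 6 of 23 and lower in 1 (7 and 1 adjusted over the list alone), with a mean of 0.34 (camera adjusted p = 0.00141; adjusted p = 0.647 with an estimated correlation). Their higher members numbered 10 without P1 replicate 1, 2 without P1 replicate 3, 3 without P14 replicate 1 or P14 replicate 3, and with all arrays 3 with no filter. Col1a1, a collagen chain, was 2.76-fold higher (1.47 ± 0.208, adjusted p = 0.00442; 4.46-fold after normexp), Col5a1 1.72-fold (adjusted p = 0.00259) and Sparc 2.01-fold (adjusted p = 0.0237; 0.0699 without P1 replicate 3; its 3 probes spanned 1.27 and their mean gave 0.52, adjusted p = 0.101), and the actin-severing gene Gsn was 1.44-fold lower (adjusted p = 0.0137).

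**Figure D3:**
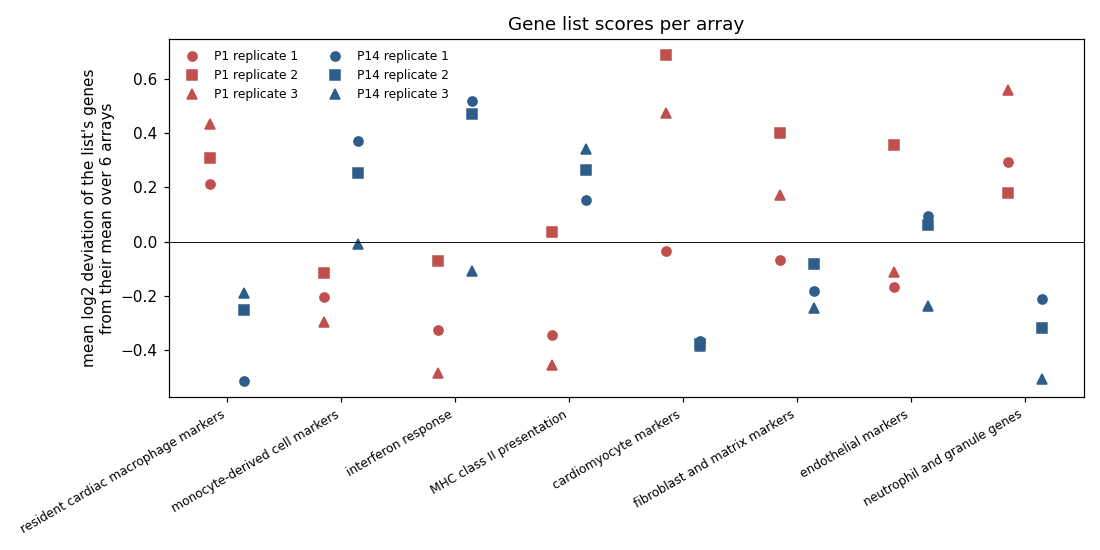
Mean log2 deviation of the genes of 8 lists from their mean over 6 arrays (vertical axis), for each array; colours give the age and shapes the replicate. P1 replicate 1 has a cardiomyocyte score of -0.03 against 0.69 and 0.47 on the other P1 arrays, and P14 replicate 3 an interferon score of -0.11 against 0.52 and 0.47 on the other P14 arrays.

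Endothelial markers did not shift as a list (0 higher and 1 lower of 17, 0 and 0 adjusted over the list alone; camera adjusted p = 0.801). The water channel gene Aqp1 was 1.74-fold lower in P1 (adjusted p = 0.0264; 0.0904 without P1 replicate 3), and at -0.40 with the mean of its probes (adjusted p = 0.167). Of 9 erythroid genes 1 was higher, Tspan33 (1.23-fold, adjusted p = 0.0363; 0.107 without P14 replicate 1), and 0 adjusted over the list alone (camera adjusted p = 0.801); its mean (-0.00297) was below 0 and camera's direction was up. Of 13 dendritic cell markers 3 were higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.841), with a mean (-0.03) below 0, and a median (0.03) and camera's direction above. Cd83, an activation marker, was 1.49-fold higher (adjusted p = 0.00758), Snn 1.70-fold (adjusted p = 0.0138; 0.0509 without P1 replicate 3) and the actin bundler Fscn1 1.33-fold (adjusted p = 0.0224; 0.0805 without P1 replicate 3). Of 5 NK and T cell markers 2 were lower, over all genes and over the list alone, namely the receptor Klrd1 (1.61-fold, adjusted p = 0.00692, with 2 of 3 P1 arrays above the floor, 2.62-fold after normexp) and perforin, Prf1 (1.36-fold, adjusted p = 0.0234; 0.0752 without P14 replicate 1), and the list did not pass (camera adjusted p = 0.141). Of 5 B cell markers Cd79b was higher (2.07-fold, adjusted p = 0.00180), also over the list alone; the list did not pass (camera adjusted p = 0.841) and its mean (0.15) and median (-0.08) differ in sign. Of 8 eosinophil and mast cell markers 0 passed, over all genes or over the list alone (camera adjusted p = 0.981), and the mean (0.11) was above 0 while camera's direction was down, with Ear3 at 0.69 ± 0.414 (adjusted p = 0.288) and Hdc at -0.02 ± 0.268 (adjusted p = 0.962). Sex-linked genes did not pass either (0 of 4, camera adjusted p = 0.607), with Xist at -0.52 ± 0.239 (adjusted p = 0.166, and a span of 1.48 over its 4 probes) and Kdm5d at -0.30 ± 0.140 (adjusted p = 0.174). This list joins Xist with genes of the Y chromosome, which a difference in sex mix would move in opposite directions. A directional test of the list therefore cannot judge whether the sexes were balanced.

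For glycolysis and hypoxia, 2 of 24 genes were higher and 4 lower in P1 (2 and 7 adjusted over the list alone), with a camera adjusted p of 0.0538. The glucose transporter Slc2a1 was 1.68-fold lower (-0.75 ± 0.109, adjusted p = 0.00485), the glycolytic enzymes Tpi1 and Pfkp were 1.33-fold and 1.31-fold lower (adjusted p = 0.0159 and 0.0196), and Pdk1, which diverts pyruvate from mitochondria, was 1.33-fold higher (adjusted p = 0.0189). The calls of Tpi1 and Pfkp were lost without P1 replicate 3 (0.0589 and 0.0670) and that of Pdk1 without P1 replicate 1 (0.0531). With the mean of its 3 probes Tpi1 had a log2 fold change of -0.12 (adjusted p = 0.351). Of 31 efferocytosis, scavenging and lysosome genes 3 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.936). Lipa, lysosomal acid lipase, was 1.68-fold higher (adjusted p = 0.00511), the scavenger receptor Marco 2.09-fold (adjusted p = 0.0337) and Pros1, a bridge to dying cells, 1.44-fold (adjusted p = 0.0224), and the receptor Lrp1 was 1.80-fold lower (adjusted p = 0.00282). Marco lost its call without P1 replicate 3 (0.109) and Pros1 without P14 replicate 1 (0.0713). Of 26 immediate-early and heat-shock genes 4 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.801). The transcription factors Klf2 and Egr3 were 1.82-fold and 1.59-fold higher (adjusted p = 0.0125 and 0.0158), and the chaperones Hsp90aa1 and Dnajb1 1.80-fold and 1.32-fold lower (adjusted p = 0.00137 and 0.02001). Egr3 lost its call without P1 replicate 3 (0.0588) and Dnajb1 without P1 replicate 1 (0.0562).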

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

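Normexp background correction, the other floors and the added cyclic loess step were chosen after seeing the data; the other alternatives were planned. Across all settings run, 0 of the 87 named calls changed direction, and 55 of the 87 held without any single array. Settings that kept all arrays ended 21: with no filter 14 (adjusted p 0.0511 to 0.107), with the mean of probes 9 (0.0603 to 0.351), with trend and robust eBayes 8 (0.0879 to 0.147), with the lower floor 3 (0.0527 to 0.0598), with normexp at offset 16 Ccl4 (0.0685) and H2-DMb2 (0.0525), and with each probe tested Isg15 (0.0563) and H2-DMb2 (0.0547). The cause was not tested. The count of genes higher in P1 ranged from 515 to 930 and that of genes lower from 536 to 883 without single arrays, lowest without P1 replicate 3; the cause was not tested, and the ranges were 40 to 59 for genes higher in P1 with log2 fold change of at least 1 and 22 to 44 for genes lower in P1 with log2 fold change of at least 1. Averaging a gene's probes moved 14 named calls by over 1.5 times, of which 8 stayed calls (Oasl2 -0.85, Top2a 0.46, Cd80 -0.34, Grb10 0.51, Hsp90aa1 -0.39, Egr3 0.32, Ccl4 0.56 and Mpo 0.71), and turned the sign of 19 of the 2105 calls. Testing each probe gave 1577 lower, and 60 with a log2 fold change of at least 1, over 19106 probes in place of 10506 genes. Normexp with offset 16 raised the counts with a log2 fold change of at least 1 to 124 higher and 95 lower, and offset 50 gave 54 lower, since removing background widens the folds of dim genes (median ratio of log2 fold changes 1.19 and 1.10).

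The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered arrays correlated at 0.160, 0.0716 and 0.130, and those of the other pairs between the ages at -0.151 to -0.0158. Each array thus correlated best with its own number in the other age, a hint from the data and not from the design. With the replicate number as a block, 1117 genes were higher and 1064 lower, and of 2105 calls 1884 remained; among lists the block changed the call of glycolysis and hypoxia (0.0284), and it gave 19 lower interferon members and 16 higher resident macrophage members.

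All 10 list calls were lost when camera's correlation was estimated. Adjusted p was then 0.571 for cell cycle, 0.566 for interferon response, 0.647 for fibroblast and matrix markers and 0.499 for each of the other 7. By fry, which asks whether a list's genes move one way on balance, adjusted p was 0.0823 for cell cycle, 0.104 for interferon response, 0.0950 for MHC class II, 0.0586 for monocyte-derived, 0.0682 for cardiomyocyte and 0.163 for fibroblast markers, past the threshold for resident macrophage, imprinted, granule and MHC class I genes, and newly so for NK and T cell markers (0.0250) and sex-linked genes (0.0398). Glycolysis and hypoxia genes, at 0.0538, passed with no filter (0.0189), array weights (0.0168), floors at 2 (0.0437) and 6 (0.0370) standard deviations and ranks (0.0482), and ranged from 0.00889, without P14 replicate 3, to 0.203 without single arrays. NK and T cell markers also passed with the stricter floor (0.0478). The cause of these changes was not tested. Of the lists not called, the number of members higher and lower without single arrays ranged over 3 to 6 and 3 to 5 for alternative activation, 0 to 2 and 1 to 4 for inflammatory, 2 to 4 and 1 to 3 for chemokine, 4 to 7 and 5 to 9 for growth factor, 0 to 2 and 1 to 7 for glycolysis, 1 to 4 and 1 to 2 for efferocytosis and for immediate-early genes, and 1 to 3 and 0 to 3 for dendritic cell markers. The 10 list calls held in every other setting run, with these ranges without single arrays: cell cycle 8.46e-06 to 0.00762, interferon 2.23e-13 to 4.81e-05, MHC class II 0.000865 to 0.0328, MHC class I 3.91e-06 to 0.000810, monocyte-derived 8.46e-06 to 0.00380, resident macrophage 9.82e-09 to 4.47e-05, imprinted 0.000188 to 0.00216, cardiomyocyte 6.27e-16 to 2.32e-06, fibroblast 2.25e-06 to 0.0191, granule 7.69e-05 to 0.00693.

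Not run were the choices that need unnormalized or detection values: neqc, a detection p filter, median scaling and cyclic loess in place of quantile normalization, and chip as a block. No background correction and the authors' normalized values, planned as alternatives, became the reported setting. Signal over background limits dim genes: the floor lies at an intensity of 126 and the most frequent value at 112.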

Other observations

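The tests of cardiomyocyte transcripts, with the comparison to other lists, and of mature neutrophil genes, and the count of dim probes that moved towards 0 or past it, were chosen after the result was seen. Single arrays differed within an age in cell-type transcripts. Erythroid genes had a mean log2 deviation of 0.39 on P14 replicate 3 and of -0.31 and -0.07 on P14 replicates 1 and 2. MHC class II genes stood at 0.04 on P1 replicate 2 against -0.34 and -0.46 on the other P1 arrays. Endothelial markers stood at 0.36 on P1 replicate 2, the array with the highest cardiomyocyte (0.69) and fibroblast (0.40) values, and at -0.17 and -0.11 on the other P1 arrays.

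The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2105 genes, as many as only 1 of the 10 splits, itself, and the highest other gave 1. It gave 10 lists at the preset correlation, and 2 of the 10 splits, itself included, gave as many: the highest other, P1 replicates 1 and 3 with P14 replicate 3 against the rest, gave 10.

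Cardiomyocyte transcripts were higher in P1, by 1.12 ± 0.308 (SE over arrays) as a list mean after normexp, fibroblast and matrix markers by 0.497 ± 0.198, and endothelial markers by 0.0959 ± 0.284; Myl2 reached an intensity of 4338 in P1 and 823.5 in P14, although the CD11b gate should remove cardiomyocytes. A lower share of myeloid cells in the P1 sorts would raise markers of other cell types, and the fibroblast markers go with that. It would raise them alike only if those cells were mixed the same way at both ages, which was not measured. The cardiomyocyte shift exceeded the endothelial shift by 1.02 ± 0.241, but without that mix the difference does not decide for or against a lower myeloid share. Cardiomyocyte RNA carried into the sort in varying amounts would make the 25 genes deviate together, and their residual correlation of 0.548 lay above 100% of 1000 random lists matched on expression. This does not single out carried RNA: endothelial markers reached 0.655, and 99.9% of the cardiomyocyte list's joint deviation came from the P1 arrays, so that explanation stays open. A difference of age in the injured muscle itself remains open and untested.

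Granule protein transcripts were higher in P1 although the gate excludes Ly6G-positive cells. More residual mature neutrophils would bring all their abundant transcripts, but 11 mature neutrophil genes, 3 of them (Retnlg, Csf3r and Fpr2) also in the granule list, had a median of -0.36 ± 0.140, the value of Mmp25 (adjusted p = 0.0363, lost without any of 5 arrays, up to 0.119), whose P1 mean lies below the floor; Retnlg (-1.63) and Il1r2 (-0.94) were also lower, and Ccrl2 (0.76) and Csf3r (0.53) higher. A part from such cells is not excluded, since the list's mean deviation on P14 replicate 3 (-0.09) lay below that on P1 replicate 3 (-0.03), and on P1 replicates 1, 2 and 3 it followed the granule list (-0.22, -0.33 and -0.03 against 0.29, 0.18 and 0.56). Several of the 11 genes were bright at both ages: Ccrl2 (intensity 5618 in P1 and 3327 in P14), Clec4d (4266 and 4774), Fpr2 (3485 and 5403) and Selplg (2094 and 2125). Such levels would hide a small share of mature neutrophils, so the median of the 11 genes does not decide whether P1 held more of them. For more immature granulocytes, 9 other genes of that stage had a median of -0.0686 ± 0.0653. This met the bound set beforehand against them (0 or below) by little more than its SE. Cebpe (-0.45, adjusted p = 0.0145, and 0.0570 without P1 replicate 3) and Trem3 (-0.42, adjusted p = 0.0441, lost without any of 5 arrays, up to 0.127) were lower and 0 were called higher. Fcnb (0.25 ± 0.0793, adjusted p = 0.0588), Gfi1 (0.20 ± 0.0603, adjusted p = 0.0529) and Serpinb1a (0.17 ± 0.0661, adjusted p = 0.110) ran upward, and the other members downward. The P14 means of these upward members lie below the floor, which understates their folds. Dstn (intensity 1818 in P1 and 1845 in P14) starts from a level that would hide a small share of such cells. The median therefore does not decide the question, and expression of granule genes by the young macrophages themselves was not tested.

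Probes of the same gene disagreed in places: of 5 Actb probes, 3 were lower in P1 by -1.78, -1.80 and -1.89 and the others by -0.36 and -0.31, and in 30 of 3920 genes with several probes the log2 fold changes spanned over 1, against a median span of 0.20. RNA integrity or labelling length may differ between the ages. Over the 3920 genes the dimmest probe relative to the brightest was lower in P1 by -0.0140 ± 0.00698, though not on every P1 array. Brightness stood in for the position of a probe along its transcript, which was not used, so this small shift does not decide the question. In the 30 genes the dimmest probe was lower relative to the brightest in 21 (70.0%, 95% exact binomial interval 50.6 to 85.3%). In 25 of the 30 (83.3%) the dimmest probe had moved towards 0, or past it, relative to the brightest. Background that was not subtracted would move it towards 0 but not past it, and the 25 include both. These counts therefore do not separate the explanations. Compression does not account for Actb, whose dim probes moved away from 0, as did 1 with a P14 intensity of 25628. Transcript ends, variants of the outbred strain, cross-hybridisation and a biological difference of age stay open and untested.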
